A study of Homo sapiens with 6 samples.

How the data were processed

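Poly(A)-enriched RNA was sequenced from 6 libraries of CT27 cells, an established human trophoblast stem cell line, taken through differentiation into extravillous trophoblast (EVT), the invasive trophoblast lineage of the placenta. Per the labels, 3 libraries carried a knockdown of TCF7L2 and 3 a control knockdown. The series description gives short hairpin RNA (shRNA) as the means of depletion. The labels give an RNeasy Plus extraction, enrichment on oligo(dT) beads, cDNA synthesis from random primers and the NEBNext Ultra II kit. They do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

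The deposited table holds TPM, a transcript abundance corrected for transcript length and scaled to one fixed total per library, which the authors had computed per gene symbol. Salmon, a tool that estimates transcript abundance, and DESeq2 1.30.1 are named in the submitters' processing notes, with the genome build hg38 and no statement of what each tool did. The annotation, the strand setting and any filter are not given in the sources used here. The table has 60880 rows with 0 repeated symbols and 0 columns outside the 6 libraries. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval or detection floor is given. TPM is also a share of a fixed total, so a change in abundant transcripts moves all other values. Members of near-identical gene families, such as CSH1 and CSH2, the CGB genes, the PSG genes, the HLA genes and the histone genes, share sequence that the authors' quantification could divide among them, and their separate values are uncertain.

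Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), for the 15235 genes with a mean TPM of at least 1 over the 6 libraries. A gene with a lower mean than that in 1 group passes only through the other group, and can then change in that direction alone. The moderated test used a mean-variance trend, was two-sided, and was adjusted by the Benjamini-Hochberg method over all genes tested. A gene is called higher, lower or changed at an adjusted p under 0.05. Fold changes are knockdown minus control on the log2(TPM + 1) scale, which understates the change of genes with low values. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01. The test covered the 24 of 27 lists with at least 5 genes tested, adjusted over those lists. Camera asks whether the members of a list moved relative to the other genes. An estimated correlation and the rotation test fry were the alternatives. The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined.

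The rule names the TCF/LEF family, and the 10 largest rises and 10 largest falls among called protein-coding genes whose groups do not overlap and whose higher group has a mean TPM of at least 5. It also names up to 4 called members of each list by size of change, or the 2 members with the highest mean TPM where fewer than 2 were called. Symbols were matched to the RefSeq table of GRCh38.p14 for gene types (89.5% of the genes tested), and gene positions come from GENCODE release 29 on GRCh38, the assembly that hg38 names. The annotation release may differ from that of the authors. XIST and Y-linked genes are not reported.

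The procedure was checked on simulated log2 values with the means and spreads of the 15235 genes and 200 changed genes. For the comparison of TCF7L2 knockdown with control, 90.0% of changes of 2 on the log2 scale, 59.5% of changes of 1 and 0 of the changes of 0.5 were recovered. Of the calls, 4.76% were false at a change of 2 and 8.46% at a change of 1, and simulated data without changes gave 0 calls. A simulated list of 25 genes shifted by 1 was called among 24 lists, together with 1 list that had not been shifted. In the real comparison 9160 genes were called, so the Benjamini-Hochberg cut is less strict and the recovered shares do not give its power. A log2 fold change of 0.33, for VGLL1, was called there. Simulated genes varied independently, while the estimated correlation within a real list reached 0.84, so the list check does not cover correlated members.

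The alternatives were a pseudocount of 0.1 or 5, no filter on low values or a mean TPM of at least 5, division by median-of-ratios size factors, and quantile normalization. Others were a robust variance estimate, library weights, the replicate number as a block, leaving out each library in turn and an adjusted p threshold of 0.01. Tests of protein-coding genes alone, and of the genes left after removing the 100 with the highest mean TPM, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.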

Results

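Transcript levels were measured in CT27 human trophoblast stem cells differentiated into EVT, in 3 libraries with TCF7L2 knockdown and 3 with control knockdown. The comparison addresses which genes depend on TCF7L2, a transcription factor of the TCF/LEF family that acts at the end of canonical Wnt signalling, during this differentiation. Sequencing depth is unknown, since TPM does not keep it. The lowest Pearson correlation of log2(TPM + 1) between libraries was 0.979 within the control group and 0.963 within the knockdown group, while correlations between the groups were from 0.876 to 0.891. For the 1489 genes with a mean TPM of at least 100, the median coefficient of variation was 5.23% between control libraries and 9.16% between knockdown libraries.

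TCF7L2 (chromosome 10, 112950250 to 113167678, plus strand, GRCh38) had 117, 89.9 and 98.6 TPM in the control libraries and 14.1, 13.9 and 17.3 TPM in the knockdown libraries. Its log2 fold change was -2.68 with a standard error of 0.13 (limma, adjusted p = 6.8e-06), and the exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. TCF7L1, a related factor, fell from 31.0 ± 1.33 to 15.1 ± 4.86 TPM (SD, n = 3; log2 fold change -1.04, adjusted p = 5.1e-03). The remaining family members were below the filter: TCF7 had a mean of 0.159 TPM in control and 1.44 in knockdown, and LEF1 0.198 and 0.433 TPM. Both family members tested were also lower after either scaling, and their median log2 fold change was -1.86, or -2.25 relative to that of all genes tested. That median includes TCF7L2, the target of the knockdown, and leaves out TCF7, whose knockdown libraries were all higher. It does not describe a response of the family.

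Of the 15235 genes tested, 9160 changed, 7275 higher and 1885 lower in knockdown, and 3626 of them changed at least 2-fold. The median gene tested had a log2 fold change of 0.40, so that the distribution on TPM as deposited was shifted upwards. After division by median-of-ratios size factors, the split was 3968 higher and 4032 lower, or 49.6% of calls higher against 79.4% before, and after quantile normalization it was 3617 higher and 3784 lower. The 1885 genes lower as deposited were all lower after median-of-ratios scaling too. This could hardly be otherwise, because that scaling lowers knockdown values relative to control (mean size factor 0.862 in control and 1.17 in knockdown). It puts only the rises to a test. After quantile normalization some falls lost the call, such as RPL3, named after its value was seen, at a log2 fold change of -0.12. Of the 7275 genes higher as deposited, 3968 were also called higher after median-of-ratios scaling and 13 were called lower after it. The median log2 fold change was 0.56 for genes with a mean TPM of 1 to 3, 0.42 for 10 to 30, 0.08 for 100 to 300 and -0.57 from 1000 upwards. For each gene list below, the median is therefore also given relative to that of all genes tested ("relative to all genes"), and the calls after median-of-ratios scaling ("after scaling") stand beside those on TPM as deposited. The same value is subtracted at every level, so the trend with level is not removed, and camera does not remove it either. Lists of abundant genes can thus look lower than genes of like level. Genes matched to the EVT markers in control TPM and transcript length had a median log2 fold change of -0.10. Counts after quantile normalization are added where they depart from either.

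**Figure D1:**
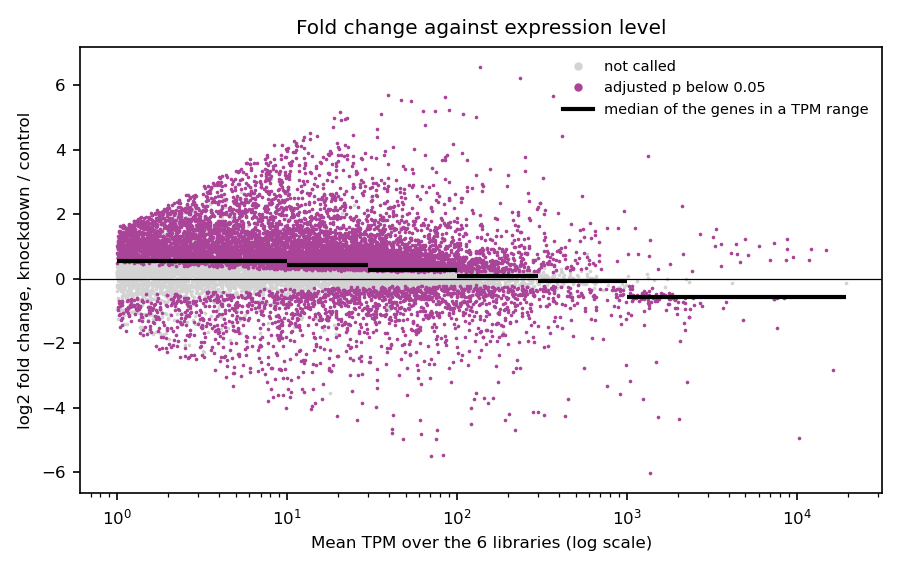
Each point is 1 gene, with its mean TPM over the 6 libraries on a log scale (horizontal) and its log2 fold change, knockdown minus control on the log2(TPM + 1) scale (vertical). Black lines are the median of all genes in a TPM range, which lies at 0.56 from 1 to 3 TPM and at -0.57 from 1000 TPM upwards.

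Camera called 10 of the 24 lists, 7 higher and 3 lower relative to the other genes. With an estimated inter-gene correlation it called 0. Each of the other 9 splits of the 6 libraries into 3 and 3 also gave list calls at the preset correlation, from 2 to 9 lists. None of those splits gave a called gene. Each holds libraries of both groups on each side in unequal numbers, and so keeps part of the knockdown difference. Their list calls thus cannot show how often camera calls a list falsely. Since 0 lists were called with an estimated correlation, a list call at the preset correlation is weak evidence by itself. List calls are therefore given with both values, and the counts of members called stand beside them.

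Markers of EVT were lower in knockdown. Of 23 members tested, 19 fell, 2 rose and 2 were not called, with the same counts when adjusted over the list alone, and 20 fell and 2 rose after scaling and 19 fell and 1 rose after quantile normalization. NOTUM, a secreted enzyme that inactivates Wnt proteins, went from 2691 ± 1.21 to 42.7 ± 16.5 TPM (SD, n = 3; log2 fold change -6.03, SE 0.28, adjusted p = 5.7e-06). HLA-G, the non-classical MHC class I molecule characteristic of EVT, went from 2884 ± 131 to 159 ± 72.2 TPM (log2 fold change -4.30, adjusted p = 5.5e-05). ASCL2, a transcription factor of the trophoblast lineage, fell from 384.5 ± 21.03 to 20.96 ± 7.86 TPM, and DIO2, a deiodinase, from 532 ± 11.6 to 29.4 ± 3.14 TPM. The exceptions, named after their values were seen, were FLT1, a VEGF receptor, which rose from 26.1 ± 3.63 to 287 ± 25.1 TPM, and PAPPA2, which rose from 0.521 ± 0.0932 to 2.37 ± 0.938 TPM but was not called after quantile normalization. The median log2 fold change of the list was -2.69, or -3.08 relative to all genes (camera, adjusted p = 8.07e-17; adjusted p = 0.364 with an estimated correlation).

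Markers of trophoblast stem cells and cytotrophoblast moved the other way. Of 22 members tested, 17 rose, 1 fell and 4 were not called (18 rose and 1 fell when adjusted over the list alone), while after scaling 14 rose and 4 fell and after quantile normalization 18 rose and 2 fell. EPCAM, an epithelial adhesion molecule, rose from 11.6 ± 0.473 to 160 ± 22.3 TPM (SD, n = 3; log2 fold change 3.67, adjusted p = 2.1e-06). LRP2, PAGE4 and PEG10 rose by log2 fold changes of 3.28, 2.99 and 2.95. VGLL1 and KRT7, at 0.33 and 0.35, turned negative without a call after scaling, and had 0.36 and 0.40, both called, after quantile normalization. GATA2 was the member that fell, with a log2 fold change of -0.80. The last 3 genes were named after their values were seen. The members of the list had a median of 1.67, or 1.28 relative to all genes (camera, adjusted p = 0.00965; adjusted p = 0.656 with an estimated correlation).

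**Figure D2:**
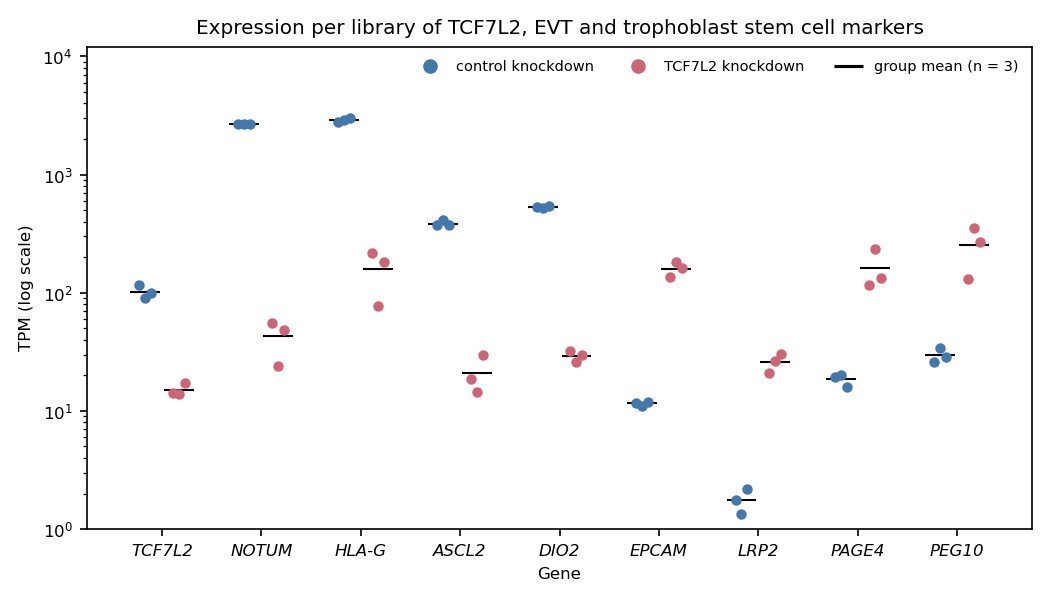
TPM on a log scale for TCF7L2, 4 EVT markers (NOTUM, HLA-G, ASCL2, DIO2) and 4 trophoblast stem cell and cytotrophoblast markers (EPCAM, LRP2, PAGE4, PEG10). Points are libraries, 3 per group, and black lines are group means. For each gene the groups did not overlap, with HLA-G at a mean of 2884 TPM in control and 159 TPM in knockdown.

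Of 9 tested markers of cell column progenitors, cells between the stem cell and EVT states, 7 rose and 2 fell, also when adjusted over the list alone, and 6 rose and 2 fell after scaling and after quantile normalization. ITGB6 rose from 0.218 ± 0.0473 to 37.6 ± 6.78 TPM and SOX15 from 1.301 ± 0.278 to 31.3 ± 7.75 TPM, and TAGLN and ITGA2 had log2 fold changes of 3.78 and 3.29. NOTCH2 and LPCAT1, named after their values were seen, fell. With a median of 1.93, or 1.53 relative to all genes, the list was not called (camera, adjusted p = 0.11).

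Markers of syncytiotrophoblast, the multinucleate hormone-secreting trophoblast, were divided. Of 28 members tested, 11 rose, 9 fell and 8 were not called, with the same counts when adjusted over the list alone, and 7 rose and 13 fell after scaling and 9 rose and 10 fell after quantile normalization. CSH1, a placental lactogen gene, fell from 19963 ± 618 to 715 ± 351 TPM (SD, n = 3; log2 fold change -4.95, adjusted p = 3.9e-05), and the near-identical CSH2 had a log2 fold change of -4.36. CSH1 and CSH2 together held 2.38% of all TPM in control and 0.0925% in knockdown. GCM1, a transcription factor of trophoblast differentiation, fell from 194.5 ± 15.4 to 41.0 ± 6.45 TPM. PSG1, of the pregnancy-specific glycoprotein family, rose from 31.0 ± 0.858 to 179.7 ± 25.1 TPM. Members of near-identical families make up much of both counts, which are thus not separate observations. CGB3, CGB5, CGB7 and CGB8 fell with CSH1 and CSH2, and PSG3, PSG4 and PSG5 rose with PSG1. CGA had 20214 ± 1247 TPM in control and 18598 ± 2602 in knockdown, and was called lower only after median-of-ratios scaling. The CGB genes, the added PSG genes and CGA were named after their values were seen. The list median was 0.13, or -0.27 relative to all genes, its mean was -0.08, and the list was not called (camera, adjusted p = 0.071). It was called lower without knockdown replicate 1 (adjusted p = 0.0372) or without knockdown replicate 2 (adjusted p = 0.0346).

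Canonical Wnt target genes changed in both directions. Of 12 members tested, 8 rose and 4 fell, also when adjusted over the list alone, and 6 rose and 4 fell after scaling and 5 rose and 4 fell after quantile normalization. NOTUM and ASCL2, described among the EVT markers, fell, while CD44, a cell surface receptor for hyaluronan, rose from 2.45 ± 0.715 to 169 ± 21.1 TPM and SOX9, a transcription factor, from 0.0545 ± 0.0131 to 4.46 ± 0.286 TPM. AXIN2, a widely used Wnt reporter gene named after its value was seen, fell from 18.6 ± 2.42 to 10.1 ± 2.47 TPM (SD, n = 3; log2 fold change -0.84, adjusted p = 6.9e-03). The median of the members was 0.71, or 0.31 relative to all genes, and their mean 0.32, and the list was not called (camera, direction lower, adjusted p = 0.983). Of 29 Wnt ligands, receptors and core components tested, 18 rose, 6 fell and 5 were not called, and 13 rose and 7 fell after scaling and 13 rose and 9 fell after quantile normalization. The ligands WNT6 and WNT10A and the co-receptor LRP5 rose by log2 fold changes of 3.97, 2.95 and 3.60, and SFRP1, a secreted Wnt antagonist, had a log2 fold change of -2.12. That list had a median of 0.72, or 0.33 relative to all genes, gave the same counts when adjusted over the list alone, and was not called (camera, adjusted p = 0.773).

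Epithelial junction genes were higher. Of 24 members tested, 16 rose, 2 fell and 6 were not called (16 rose and 3 fell when adjusted over the list alone), and 14 rose and 6 fell after scaling and 16 rose and 2 fell after quantile normalization. CLDN1, a tight junction claudin, rose from 1.67 ± 0.186 to 66.6 ± 13.3 TPM, and MARVELD3 and ST14 rose by log2 fold changes of 3.86 and 3.85. The list median was 1.16, or 0.76 relative to all genes (camera, adjusted p = 0.0261; adjusted p = 0.666 with an estimated correlation). Of 13 mesenchymal genes tested, 7 rose and 6 fell, on TPM as deposited, after scaling and when adjusted over the list alone. ACTA2, SNAI2 and TGFBI rose by log2 fold changes of 4.05, 3.83 and 3.51, while MMP2 went from 1675 ± 120 to 146 ± 49.5 TPM (log2 fold change -3.57). That list had a median of 1.58, or 1.18 relative to all genes, and a mean of 0.43, and was not called (camera, direction lower, adjusted p = 0.196). Some members stand on more than 1 list, so the lists are not separate observations. FN1, ITGA5 and MMP2, which all fell, are on the mesenchymal and the EVT lists. EPCAM, CDH1 and KRT18 are on the epithelial junction and the stem cell and cytotrophoblast lists.

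Of 24 matrix, protease and invasion genes tested, 12 fell, 10 rose and 2 were not called, with the same counts when adjusted over the list alone, and 14 fell and 8 rose after scaling and 12 fell and 10 rose after quantile normalization. LAMA4, a laminin chain, fell from 228.5 ± 19.8 to 13.9 ± 4.97 TPM and ADAM19, a metalloproteinase, from 835 ± 98.2 to 63.5 ± 17.2 TPM. PLAU, the urokinase protease, and its receptor PLAUR rose by log2 fold changes of 2.87 and 3.73. Their median was -0.23, or -0.63 relative to all genes (camera, lower, adjusted p = 0.00965; adjusted p = 0.656 with an estimated correlation). Of 11 YAP/TEAD target genes tested, 8 rose, 1 fell and 2 were not called, also when adjusted over the list alone, and 7 rose and 1 fell after scaling and after quantile normalization. F3, tissue factor, rose from 2.32 ± 0.413 to 124 ± 38.3 TPM, and AXL, CCN1 and ANKRD1 rose by log2 fold changes of 4.93, 3.88 and 3.60. The median of that list was 1.61 relative to all genes (camera, adjusted p = 0.0221; adjusted p = 0.656 with an estimated correlation). Of 10 TGF-beta and BMP target genes tested, 5 rose, 2 fell and 3 were not called, with the same counts when adjusted over the list alone, and 3 rose and 3 fell after scaling and after quantile normalization (median 0.44, or 0.04 relative to all genes; camera, adjusted p = 0.983). BAMBI and SERPINE1 rose by log2 fold changes of 1.55 and 1.29, and ID4 had one of -1.23.

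Of 26 proliferation genes tested, 21 rose, 2 fell and 3 were not called (22 rose and 2 fell when adjusted over the list alone), and 19 rose and 3 fell after scaling and 18 rose and 2 fell after quantile normalization. TYMS, TOP2A and CDK1, which act in DNA synthesis and mitosis, rose by log2 fold changes of 1.82, 1.82 and 1.81, with TOP2A at 4.02 ± 0.585 TPM in control and 16.7 ± 1.31 in knockdown. CCNE1, cyclin E1, fell from 974 ± 80.7 to 143 ± 9.93 TPM, and CCNB1, named after its value was seen, fell as well. Their median was 1.06, or 0.66 relative to all genes (camera, adjusted p = 0.0159; adjusted p = 0.656 with an estimated correlation). Of 9 cell cycle inhibitors tested, 3 rose, 1 fell and 5 were not called, also when adjusted over the list alone, and 2 rose and 5 fell after scaling and after quantile normalization. CDKN1A (p21) rose from 92.4 ± 1.96 to 364 ± 39.5 TPM and CDKN1C (p57) fell from 3143 ± 149 to 1224 ± 108 TPM. CDKN2A had a log2 fold change of 1.44, and CDKN2B, at 0.77, was not called after scaling. That list had a median of 0.13, or -0.27 relative to all genes, and was not called (camera, adjusted p = 0.666).

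Of 16 p53 target genes tested, 15 rose and 1 was not called, also when adjusted over the list alone, and 14 rose after scaling and 15 after quantile normalization. FAS, a death receptor, had 0.0171 ± 0.0089 TPM in control and 11.4 ± 3.49 in knockdown (SD, n = 3; log2 fold change 3.58, adjusted p = 1.5e-05). FDXR and ZMAT3 rose by log2 fold changes of 2.50 and 1.92. The list median was 1.47, or 1.07 relative to all genes (camera, adjusted p = 0.000104; adjusted p = 0.364 with an estimated correlation). Of 16 genes of the unfolded protein and integrated stress responses, 9 rose, 3 fell and 4 were not called, with the same counts when adjusted over the list alone, and 7 rose and 7 fell after scaling and 9 rose and 6 fell after quantile normalization (median 0.50, or 0.10 relative to all genes; camera, adjusted p = 0.894). The serine and asparagine synthesis genes PSAT1 and ASNS rose by log2 fold changes of 2.09 and 1.86, and CHAC1 and DDIT3 by 1.41 and 1.34.

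Of 16 hypoxia and glycolysis genes tested, 6 rose, 5 fell and 5 were not called (6 rose and 6 fell when adjusted over the list alone), and 5 rose and 9 fell after scaling and 5 rose and 5 fell after quantile normalization (median -0.17, or -0.57 relative to all genes; camera, adjusted p = 0.0679). EGLN3, VEGFA and HK2 rose by log2 fold changes of 3.44, 1.92 and 1.56, and PFKFB4 had one of -1.52. Of 17 cholesterol synthesis genes tested, 4 rose, 2 fell and 11 were not called (2 rose and 2 fell when adjusted over the list alone), and 2 rose and 9 fell after scaling and 3 rose and 3 fell after quantile normalization (median 0.08, or -0.32 relative to all genes; camera, adjusted p = 0.165). SC5D and IDI1 had log2 fold changes of 0.87 and 0.77, and MSMO1 and LDLR of -0.75 and -0.71. Of 10 immediate early genes tested, 5 rose, 2 fell and 3 were not called, also when adjusted over the list alone, and 3 rose and 4 fell after scaling and 3 rose and 2 fell after quantile normalization (median 0.28, or -0.12 relative to all genes; camera, adjusted p = 0.881). JUN and EGR1 rose by log2 fold changes of 3.19 and 1.23, whereas FOS had -2.15 and FOSB fell from 15.5 ± 1.75 to 7.34 ± 1.49 TPM.

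Genes of MHC class I and antigen processing were lower. Of 12 members tested, 9 fell and 3 rose, on TPM as deposited, after scaling and when adjusted over the list alone. Besides HLA-G, the peptide transporter genes TAP1 and TAP2 had log2 fold changes of -2.02 and -2.10, and PSMB9, an immunoproteasome subunit, fell from 13.2 ± 1.96 to 1.04 ± 0.273 TPM. HLA-A, HLA-B and TAPBP, named after their values were seen, rose, and HLA-A was not called after quantile normalization, which left 2 higher and 9 lower. Their median was -0.91, or -1.31 relative to all genes (camera, adjusted p = 1.97e-05; adjusted p = 0.423 with an estimated correlation). Of 20 type I interferon response genes tested, 16 rose and 4 were not called, also when adjusted over the list alone, and 10 rose after scaling and 9 after quantile normalization. OAS1, OAS3 and XAF1 rose by log2 fold changes of 3.25, 2.78 and 2.62, and IFI6 rose from 673 ± 39.9 to 3565 ± 1692 TPM. The knockdown libraries differed widely, with IFI6 at 1616, 4422 and 4657 TPM. The median was 1.37, or 0.97 relative to all genes, the estimated correlation between members was 0.84, and the list was not called (camera, adjusted p = 0.0551).

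**Figure D3:**
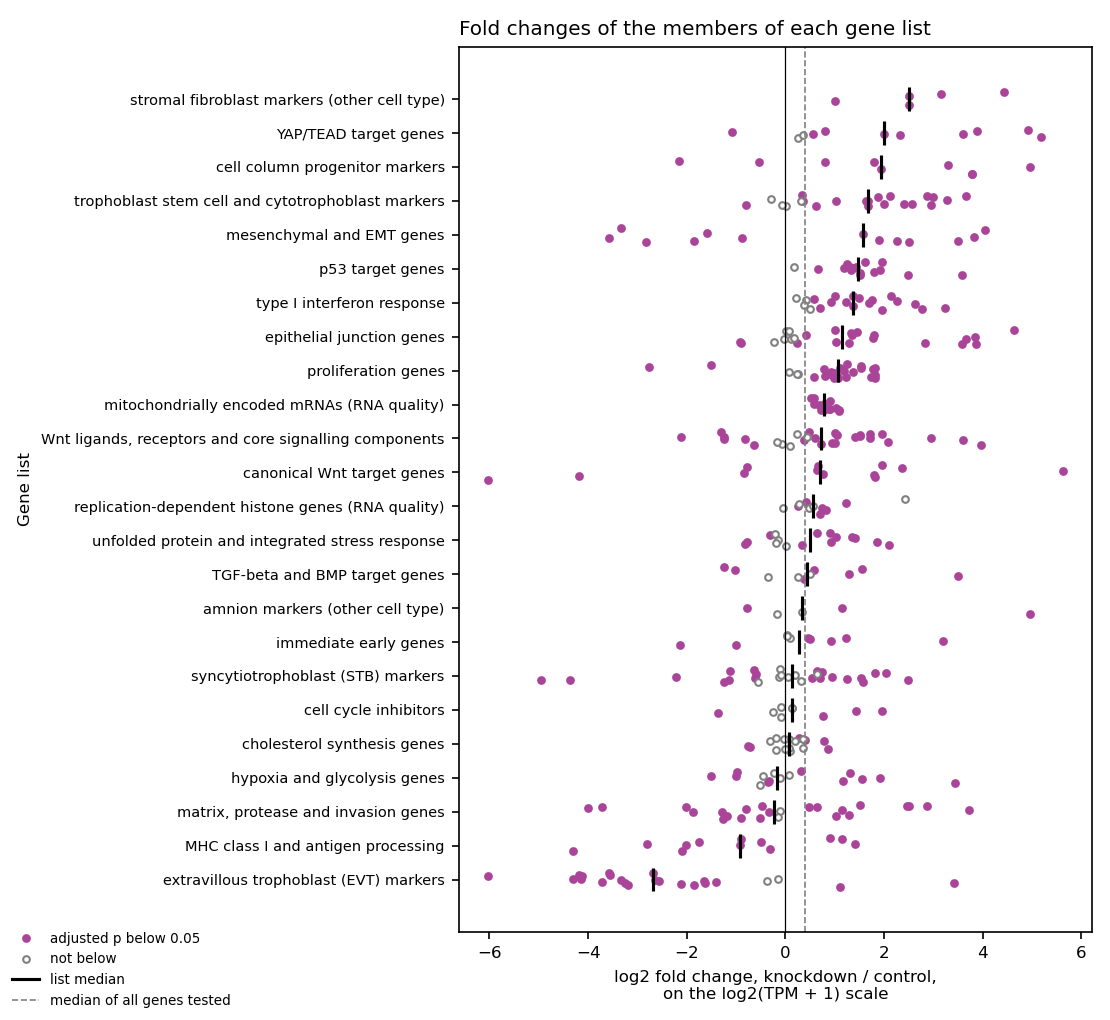
Log2 fold change, knockdown minus control on the log2(TPM + 1) scale (horizontal), of every tested member of the 24 lists with at least 5 genes tested (vertical). Filled points had an adjusted p under 0.05 on TPM as deposited, black bars are list medians, and the dashed line is the median of all genes tested, at 0.40. EVT markers have the lowest median, at -2.69.

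Among markers of other cell types, 5 of 10 stromal fibroblast genes were tested, and all 5 rose, on TPM as deposited, after scaling and when adjusted over the list alone, and 4 after quantile normalization. COL1A2, a type I collagen chain, rose from 35.7 ± 3.37 to 793 ± 100.2 TPM, while COL1A1, LUM and COL3A1 reached means of 31.8, 8.82 and 6.83 TPM in knockdown. LUM and COL3A1, at 0.0942 and 0.331 TPM in control, passed the filter only through their knockdown values. The count of rises and the list test are thus partly set by the filter. That list had a median of 2.51, or 2.11 relative to all genes (camera, adjusted p = 0.0168; adjusted p = 0.364 with an estimated correlation). The filter acts in the same way on rises in the other lists. SOX9, FAS, ITGB6, ACTA2, SNAI2, AXL, ANKRD1, WNT10A, OAS1 and EGR1 were among the members with a mean below 1 TPM in control. For falls, VWF had a mean below 1 TPM in knockdown. Of 4 endothelial genes tested, VWF, CDH5 and PECAM1 fell by log2 fold changes of -2.16, -1.02 and -0.87 and 1 was not called, in each adjustment and scaling (median -0.95, or -1.34 relative to all genes). Of 2 leukocyte genes tested, CSF1R had a log2 fold change of 0.47, which was called on TPM as deposited and when adjusted over the list alone, was 0.07 after median-of-ratios scaling and -0.0884 after quantile normalization without a call, and was not called without control replicate 2 or without knockdown replicate 1 or 2. The other, CD68, had -0.27 and was called lower after either scaling but not on TPM as deposited; their median was 0.10, or -0.30 relative to all genes. Of 5 amnion genes tested, ITGB6 and VTCN1 rose (VTCN1 not after quantile normalization), BMP4 fell and 2 were not called (3 rose and 1 fell when adjusted over the list alone), and 2 rose and 2 fell after scaling and 1 rose and 2 fell after quantile normalization (median 0.34, or -0.06 relative to all genes; camera, adjusted p = 0.983).

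All 13 mitochondrially encoded mRNAs, fixed beforehand as a possible sign of RNA quality, rose on TPM as deposited, also when adjusted over the list alone. A change in the cells could move them as well, and the cause was not tested. After median-of-ratios scaling 3 rose, and after quantile normalization 12 did. MT-ND6, MT-ND5 and MT-ND4L had log2 fold changes of 1.10, 1.09 and 1.03, and MT-CO2 had 0.91, which was not called after median-of-ratios scaling (0.47) but was after quantile normalization (1.08). That list had a median of 0.79, or 0.39 relative to all genes (camera, adjusted p = 0.0261; adjusted p = 0.751 with an estimated correlation). Mitochondrial rows held 9.59 ± 0.669% of all TPM in control and 17.5 ± 2.50% in knockdown (SD, n = 3). Of 11 replication-dependent histone genes tested, also fixed as a sign of RNA quality, 6 rose and 5 were not called, also when adjusted over the list alone, and 3 rose and 1 fell after scaling and 2 rose after quantile normalization; the list had a median of 0.56, or 0.17 relative to all genes, and was not called (camera, adjusted p = 0.401). H4C8 and H2BC8 had log2 fold changes of 1.22 and 0.82, of which H2BC8 was not called after scaling, and H2BC4 and H2BC21 had 0.75 and 0.70, of which H2BC21 was not called after quantile normalization.

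The 10 largest rises that the naming rule took began with C19orf33, from 1.93 ± 0.639 to 271 ± 25.1 TPM (SD, n = 3; log2 fold change 6.55, adjusted p = 1.2e-06). OLR1, a scavenger receptor for oxidized lipoprotein, rose from 5.34 ± 0.409 to 468 ± 15.9 TPM, OXTR, the oxytocin receptor, from 0.5145 ± 0.102 to 78.4 ± 16.3 TPM, and MT2A, a metallothionein, from 13.4 ± 3.23 to 726 ± 114 TPM. CD44, GPRC5A, COL17A1, S100A16, SULF2 and F3 followed, with log2 fold changes from 5.63 to 5.19. The 10 largest falls began with NOTUM and GNG4, a G protein gamma subunit, which went from 139 ± 3.85 to 2.12 ± 0.405 TPM (log2 fold change -5.50, adjusted p = 7.7e-07). FAT2, MYL4, CSH1, ACAN, PIPOX, PDE6H, PLXDC2 and HUNK followed, with log2 fold changes from -4.96 to -4.67. All 20 genes were called in the same direction after median-of-ratios scaling and after quantile normalization. The former lowers fold changes throughout, so for the falls it is no check.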

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

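All tests in the next 3 paragraphs were chosen after the result they concern had been seen, except the test of transcript length and the other splits of the libraries.

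More genes were higher than lower in knockdown, with a median log2 fold change of 0.40. A few abundant genes were tested as the cause by removing the 100 genes with the highest mean TPM and rescaling the rest: the median was still 0.34, which argues against it. Transcript length bias is argued against too, since the lowest median over 5 equal classes of transcript length was 0.37 (86.3% of the genes tested had a length). Background from non-coding RNA stays open. At a mean TPM of 1 to 3, genes with a RefSeq type other than protein-coding had a median of -0.0907 relative to protein-coding genes (95% bootstrap interval over genes -0.159 to -0.00736). At 10 to 30 TPM, however, their median was 0.59 against 0.42. The 2 classes held 914 and 1478 of the 3334 genes at 1 to 3 TPM. Genes without a RefSeq type, which could hold such background, were left out. Library depth, which TPM does not keep, was not tested. A less concentrated transcriptome in knockdown cells stays open too: the 500 most abundant genes of each library held 62.1 ± 1.41% of TPM in control and 55.2 ± 1.67% in knockdown (SD, n = 3), and 13715 ± 121 and 15903 ± 465 genes had a TPM of at least 1. These values go with it, but they partly restate the shift and do not tell a change in the cells from one in the libraries.

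The loss of EVT markers might come from mixing, with unchanged EVT diluted by cells that lack the markers. All markers would then keep one share of their control TPM within a library. The shares of the 19 markers called lower had an SD of 1.15 between markers and a median SD of 0.47 within a marker (log2 share relative to the median marker of the library), a ratio of 2.47. ITGA5 kept 27.8 ± 0.772% and DIO2 5.52 ± 0.590% (SD, n = 3), a pair named after the values were seen. This argues against such dilution as the whole cause. A swap of labels between the groups is argued against by 0 knockdown libraries with a TCF7L2 TPM above the lowest control library. Possible signs of a difference in RNA quality go with the loss: mitochondrial rows held 9.59% of TPM in control and 17.5% in knockdown, and 7SK had 99.2 ± 15.5 and 342 ± 161 TPM. Of the 13 mitochondrial mRNAs, 3 were called higher after median-of-ratios scaling and 12 after quantile normalization. Lower quality that acts by transcript length and level would lower similar genes alike. The 23 markers tested had a median log2 fold change of -2.59 relative to genes within 2-fold in control TPM and 1.5-fold in transcript length (95% bootstrap interval over markers -3.45 to -1.73; at least 7 such genes per marker), which argues against it as the whole cause. RNA quality that acts on single transcripts was not tested and stays open. An effect of TCF7L2 on differentiation, an effect of the shRNA on other genes, and a mixture with cells that express some of the markers stay open too, since the labels do not say which shRNA each library carried and no undifferentiated library was analysed here.

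The rise of stromal fibroblast markers might come from fibroblasts among the knockdown cells. Such cells bring their other abundant transcripts, yet 0 of the other 9 markers reached 10% of the mean knockdown TPM of COL1A2. The nearest was COL1A1 at 4.01%, and 5 of the 9 (DCN, PDGFRA, PDGFRB, THY1 and COL6A3) stayed below a mean TPM of 1. VIM, which fibroblasts express strongly, had 2.78 ± 0.380 TPM in knockdown (SD, n = 3). A change of collagen genes within the trophoblast cells stays open and was not tested.

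The 6 libraries allow only 10 splits into 3 and 3, too few for a share under 0.05, and the real split was the 1 split of 10 with the largest value for each count. It gave 9160 genes past the threshold, 7275 higher, 1885 lower and 3626 at least 2-fold changed, where the highest of the other splits gave 0 for each. It gave 10 gene lists, where the other splits gave from 2 to 9. Every other split mixes libraries of both groups on each side. The knockdown difference then adds to the spread within a side, so 0 genes called was close to fixed in advance. Part of that difference also stays between the sides, so these splits are no null for the lists either.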

How the results depend on the processing

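The TCF7L2 log2 fold change was called lower under every alternative run, between -3.10 and -2.41. The count of genes past the threshold stayed within 1.5 times of 9160 under every alternative run, from 6655 at an adjusted p threshold of 0.01 to 9947 with library weights. Genes higher in knockdown numbered 3968 after median-of-ratios scaling and 3617 after quantile normalization, and genes lower numbered 4032 and 3784. Both scalings centre the distribution by construction, which accounts for the move. Genes at least 2-fold changed numbered 1799 with a pseudocount of 5, which shrinks low genes, and 2311 with a mean TPM of at least 5, which tests fewer genes. Of the alternatives chosen after seeing the data, protein-coding genes only gave 8082 genes past the threshold, and removing the 100 most abundant genes gave 9130.

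With an estimated correlation the adjusted p of the EVT list was 0.364, that of the stem cell and cytotrophoblast list 0.656, and 0 lists were called. The rotation test fry, which does not compare a list with other genes, called 20. The syncytiotrophoblast list turned to higher, without a call, after quantile normalization (0.782) and with fry (0.292), and leaving out 1 library gave adjusted p values from 0.0346 to 0.463. The Wnt target list turned to higher without a filter (0.395), after median-of-ratios scaling (0.431), after quantile normalization (0.749) and with fry (0.00011), where it was called. The cause was not tested.

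The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.077, -0.10 and 0.0058, and 2 of 6 libraries correlated best with their own number. With the number as a block, 8488 genes passed the threshold, and 11 lists. Leaving out each library gave 7646 to 8874 genes. Of 1638 values of 110 other named genes under the alternatives, 1624 kept their direction and side of the threshold, 11 lost the call, 2 gained it and 1 turned, CSF1R at -0.0884 after quantile normalization. Most of these genes were named for large changes among the calls of the main fit, so this count does not speak for all genes. Of the 7275 genes called higher, only 3968 kept that call after median-of-ratios scaling. Summing TPM per symbol was not run, because no symbol is repeated. With depth unknown, no limit of detection can be given for genes near 0.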

Other observations

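The gene groups in the next paragraphs were chosen after seeing the data, so their counts describe these libraries and are not independent evidence. Of 13 hemidesmosome and basal epithelial genes tested, 12 rose and 1 fell, and 11 rose and 1 fell after median-of-ratios scaling and after quantile normalization (camera over the added lists, adjusted p = 0.000203; adjusted p = 0.12 with an estimated correlation). COL17A1, a hemidesmosome collagen, rose from 1.34 ± 0.439 to 106 ± 12.3 TPM (SD, n = 3), the laminin-332 chains LAMA3, LAMB3 and LAMC2 had log2 fold changes of 4.32, 4.38 and 2.83, and the keratins KRT17 and KRT15 of 3.79 and 2.97. CD151, a tetraspanin, was the member that fell. All 10 pregnancy-specific glycoprotein genes tested rose, 9 after median-of-ratios scaling and 10 after quantile normalization (adjusted p = 4.17e-05; adjusted p = 0.12 with an estimated correlation), with PSG5 at 383 ± 4.60 TPM in control and 1139 ± 70.7 in knockdown. These genes are near-identical, so the division of reads among them is uncertain.

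ERBB2, a receptor of the EGF receptor family, went from 380.1 ± 31.6 to 50.5 ± 10.9 TPM and ERBB3 from 116 ± 5.88 to 64.75 ± 3.42 TPM, while EGFR rose from 73.4 ± 13.1 to 271 ± 62.6 TPM and the ligand gene AREG from 0.155 ± 0.0691 to 41.05 ± 5.999 TPM. Of 6 genes of this family tested, 4 rose and 2 fell in each scaling, and the list was not called (camera, adjusted p = 0.8). Of 8 metallothionein genes tested, 5 rose, 4 after median-of-ratios scaling and 5 after quantile normalization, without a list call (adjusted p = 0.098). Of 30 cytosolic ribosomal protein genes, 28 were called lower on TPM as deposited and 30 after median-of-ratios scaling (adjusted p = 1.49e-20 as deposited; adjusted p = 0.15 with an estimated correlation). After quantile normalization only 8 were called lower and 2, RPS16 and RPS19, higher, and the median log2 fold change was -0.09 against -0.63 as deposited, so the fall of this group depends on the scaling. Ribosomal protein genes held 13.0 ± 0.757% of all TPM in control and 8.49 ± 0.639% in knockdown.

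The non-polyadenylated small nuclear RNA 7SK had 99.2 ± 15.5 TPM in control and 342 ± 161 in knockdown, in libraries enriched for polyadenylated RNA. The near-identical histone genes H2AC18 and H2AC19 had 0 and 90.8 TPM in control replicate 1 but 104.9 and 0 TPM in control replicate 3, with similar sums.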
